A study of Mus musculus with 15 samples.

How the data were processed

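Total RNA from mouse CD4 T cells (strain C57/B6) was isolated with Trizol, labelled with Cy3 using a locked nucleic acid labelling kit, and hybridised to one-colour Agilent arrays of a custom design, per the labels; the series design gives 50 ng of RNA. Each of the 15 deposited scanner files holds the intensity of 15665 spots, with background and spatial trend subtracted by Feature Extraction 10.1.1.1 per the file headers (10.6 per the submitters' processing notes). The deposited value table holds log2 values for 2191 of the 2500 probes. How the authors made it is not given in the sources used here. On 14 arrays its columns had the ranks of the median spot brightness (Spearman correlation at least 0.999) and nearly the same sorted values in every column, as quantile normalization without background subtraction gives. Its column medians lay between 4.38 and 4.41, and its exact scale and centring stay unknown. The column of the first 42 h array matched its scanner file at only 0.459.

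Control spots and spots marked as non-uniform or population outliers were left out, and saturated spots would have been kept (there were 0). The processed signal was averaged over the spots of a probe, divided by the 75th percentile of the array over the 558 probes detected on all 15 arrays, floored at 0.607% of that percentile (the 5th percentile of detected scaled values) and taken to log2. A probe counted as detected when more than 50% of its spots were well above background, and was tested when detected on both arrays of a group. This left 911 probes. Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with group as the only term, all 15 arrays in the fit, 7 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05 within each comparison. Groups, tests, alternatives and the rule for named probes were fixed before the data were examined. That rule took, for each comparison, the largest changes in each direction among probes past the threshold and changed the same way on both slides. For the single day 7 array, both values of the other group had to lie on one side of its value instead. IDs were held to 2 per direction because no table used here names them.

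Tested on simulated data for 65 h against naive, with 200 changed probes, the procedure recovered 4% of probes changed by 1 log2 and 43% of those changed by 2 log2 among 858 probes with all 15 arrays, and 29% and 58% among 882 without the first 42 h array. Of the calls, 7.84% and 3.33% were false. Each simulated array took the residual SD of a probe over all groups. With all 15 arrays that SD includes the spread of the 42 h pair, described below. Those shares therefore do not show recovery at the spread of the naive and 65 h arrays alone. Slides were read from the file headers as batches. The overall signal was tested with an exact permutation test of the array values.

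Lists of miRNAs fixed beforehand (the miR-17 cluster and its paralogs, activation-induced, quiescence-associated, the let-7, miR-29, miR-30, miR-26, miR-15/16, miR-23/24/27 and miR-181 families, the Dlk1-Dio3 and Sfmbt2 clusters, passenger strands, viral probes and markers of other cells and tissues) were not tested, since no table used here pairs probes with names. The set tests and the mean over all probes of a miRNA were therefore not run. The alternative on mean spot signal was run on median spot signal, the column the files hold. Other alternatives changed the scaling, floor, filter, variance model, slide or replicate block and the arrays in the fit.

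Patterns weighed in the closing section were found in these data, and their tests were revised along the way. The pattern of probes with 1 spot was first drawn over all probes outside the value table, with a median difference from matched probes of -0.90 log2 and a median of 0.62 for probes with 5 spots, and was then redrawn. The brightness of blank spots on the first 42 h array was first taken after background subtraction, which cannot show a raised surface, and raw values replaced it. A test of the 1-spot probes against array brightness was first read as favouring that explanation, then set to undecided, because an offset between slides gives the same outcome, and then replaced by a comparison within slides. Another pattern, the lower overall signal, was tested against the brightness of the corner control spots (-0.094 log2) and is given only as values.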

Results

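MicroRNAs, short RNAs that repress messenger RNAs through base pairing, were measured in mouse CD4 T cells taken from spleen and lymph nodes. The series followed how their levels moved during activation in culture, during rest in IL-2, and after restimulation. Naive cells gave 2 arrays. Cells held on plate-bound antibodies against CD3, part of the T cell receptor complex, and against the costimulatory receptor CD28 gave 2 arrays each at 6, 12, 24, 42 and 65 h. Cells stimulated for 65 h and then rested to day 7 gave 1 array, and rested cells restimulated for 18 h gave 2 arrays. The 15 one-colour arrays lay on 2 slides, each holding 1 array of every group except that the day 7 array was on slide 1 only. The files used here do not pair the probe IDs with miRNA names, so probes appear by ID. On 14 arrays 640 to 950 of the 2500 probes were detected above background, and the number of arrays limits the precision of every value below. The labels do not say whether the arrays of a group came from separate mice or cultures, so p-values measure only the spread between these arrays, which may be technical.

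The first 42 h array stood apart from all others in its scanner file. It had 2146 probes above background, a median spot brightness of 466 against 21 to 23 elsewhere, and 49.6% of its spots marked as non-uniform. Across probes its scaled signal correlated with the second 42 h array at r = 0.759, where the arrays of the other pairs reached 0.942 to 0.987 (probes are not independent replicates). All groups share one estimate of the spread in limma, so this pair widened the error of every comparison: the median SE of a log2 fold change at 65 h was 0.70 with all 15 arrays and 0.44 without that array. Counts are therefore given for all 15 arrays, as fixed before the data were examined, and beside them without the first 42 h array.

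**Figure D1:**
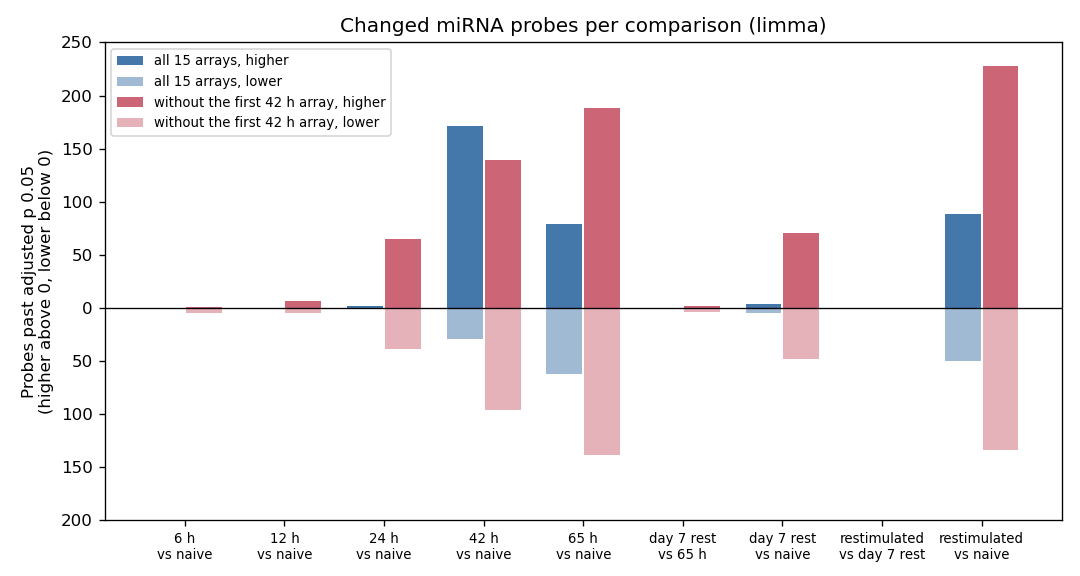
Number of probes past an adjusted p of 0.05 in limma per comparison, with higher probes above 0 and lower probes below 0. Blue bars use all 15 arrays and red bars leave out the first 42 h array; at 65 h the totals are 141 and 326.

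At 6 h and 12 h after activation few probes passed the test. With all 15 arrays limma called 0 of 911 tested probes at 6 h, with 16 at an unadjusted p under 0.05, and 0 at 12 h, with 44. Without the first 42 h array 1 probe rose and 5 fell at 6 h, and 7 rose and 5 fell at 12 h, out of 882 tested. All 6 and all 12 of these probes went the same way on both slides, nearly fixed by their selection on the mean of both slides. With the second 42 h array left out in its place, the counts were 6 and 10. At 12 h 124 of the 882 had an unadjusted p under 0.05 in that fit, and at 6 h 42. With the slide as a block and no first 42 h array 5 were higher and 6 lower at 6 h, and 15 higher and 8 lower at 12 h (62 and 220 unadjusted). Changes of 1 log2 were mostly missed in simulated data, so the low counts do not show that few probes changed. Leaving out the first 12 h array gave 1 call at 12 h.

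At 24 h the probes UCSF033_000797 and UCSF033_000796 rose above naive cells. UCSF033_000797 was higher by 3.85 log2 (SE 0.56, limma adjusted p = 0.0254, n = 2 arrays each), a 14.4-fold difference, with 3.48 on slide 1 and 4.22 on slide 2. UCSF033_000796 was higher by 3.43 log2 (SE 0.47, adjusted p = 0.0254). No probe fell with all 15 arrays, while 109 had an unadjusted p under 0.05. Leaving out the first 42 h array, 65 probes rose and 39 fell, and both named probes were among them. All 104 went the same way on both slides, as their selection nearly fixes. With the slide as a block as well, 113 were higher and 135 lower, so the more frequent direction turned. The authors' value table gave 50 higher and 51 lower out of 719 probes. Across all probes the fold changes of the slides correlated at r = 0.728. The count rested on single arrays: it was 99 without the second 42 h array, and 7 without either restimulated array. It was 0 without either naive, 6 h, 24 h or 65 h array, where 50 to 96 probes had an unadjusted p under 0.05. With quantile normalization 1 probe was higher and 5 were lower, and with the percentile taken over all probes 0 passed (76 unadjusted).

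At 42 h UCSF033_000843 rose 32.6-fold over naive cells, by 5.03 log2 (SE 0.73, limma adjusted p = 0.00460, n = 2 each), and UCSF033_000421 rose by 4.94 log2 (SE 0.57, adjusted p = 0.00182). UCSF033_001298 fell by 3.74 log2 (SE 0.63, adjusted p = 0.00796) and UCSF033_000781 by 3.09 log2 (SE 0.71, adjusted p = 0.0170). Leaving out the first 42 h array, the differences were 5.65 for UCSF033_000843, 4.14 for UCSF033_000421, -3.76 for UCSF033_001298 and -2.36 for UCSF033_000781, all still past the threshold. UCSF033_000421 was 3.77 higher on slide 1 and 6.10 on slide 2, the slide of that array, and 2.46 higher in the value table. Leaving out the second 42 h array, they were 4.36, 5.68, -3.77 and -3.87 in the same order. In all, 171 probes rose and 29 fell with all 15 arrays, and 15 of those 29 were probes with 1 spot. Without the first 42 h array the second array alone, assumed to vary like the other groups, gave 139 higher and 96 lower, and 138 of the 200 calls were shared, in the same direction. The direction of the calls differed between scalings: 18 were higher and 174 lower with the percentile over all probes. Quantile normalization gave 34 and 128, and no scaling gave 0 (95 unadjusted). These fits all hold the first 42 h array, so its part is not separated from that of the scaling. The median of all tested probes lay 1.17 log2 above naive with all 15 arrays and 0.30 without that array. The value table gave 120 and 122, but its column for that array does not match the scanner file. Of the 200 calls 196 went the same way on both slides, and the fold changes of the slides correlated at r = 0.321 across probes. The count was 500 without the second 42 h array, 13 and 10 without the first or second naive array, 130 and 127 without the first or second 6 h array, and 126 and 128 without the first or second 24 h array.

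At 65 h activated cells differed from naive cells at 141 of 911 probes, of which 79 rose and 62 fell. UCSF033_000843 rose 41.9-fold, by 5.39 log2 (SE 0.73, limma adjusted p = 0.00192, n = 2 each), with 5.41 on slide 1 and 5.37 on slide 2. UCSF033_000798 rose 26.7-fold, by 4.74 log2 (SE 0.76, adjusted p = 0.00351). UCSF033_000782 fell by 5.55 log2 (SE 0.55, adjusted p = 0.00114). In the value table the log2 differences of these 3 probes were 3.91, 4.21 and -6.04, in the same order. UCSF033_000784 was detected on both naive arrays and not well above background on either 65 h array, and was at least 34.2-fold lower (adjusted p = 0.00331). Such a bound sets the mean of the brighter group against, per array, the lowest signal among probes well above background or the probe's own, whichever is higher.

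All 141 probes went the same way on both slides at 65 h, which their selection on the mean of both slides nearly fixes. Over all tested probes, called or not, the fold changes of the slides correlated at r = 0.875. Without the first 42 h array 188 probes rose and 138 fell, and these held all 141 calls in the same direction. Probes with 1 spot, all outside the value table, made up 31 of the 62 that fell with all 15 arrays and 59 of the 138 without the first 42 h array, against 0 of the 79 and 1 of the 188 that rose. The slide as a block gave 101 higher and 100 lower. The median of all 911 tested probes lay 0.49 log2 above naive under the scaling used, so directions are relative to that shift. In the value table it lay 0.06 above, but over 719 probes, which hold none with 1 spot. Under the scaling used, without the first 42 h array, the 693 tested probes of the value table had a median of 0.71. With the percentile over all probes 23 were higher and 64 lower, after quantile normalization 45 and 107, 105 and 143 with the deposited values, and without scaling 0 and 14. The count was 298 without the second 42 h array, 52 and 33 without the first or second naive array, and 49 and 52 without the first or second 65 h array.

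**Figure D2:**
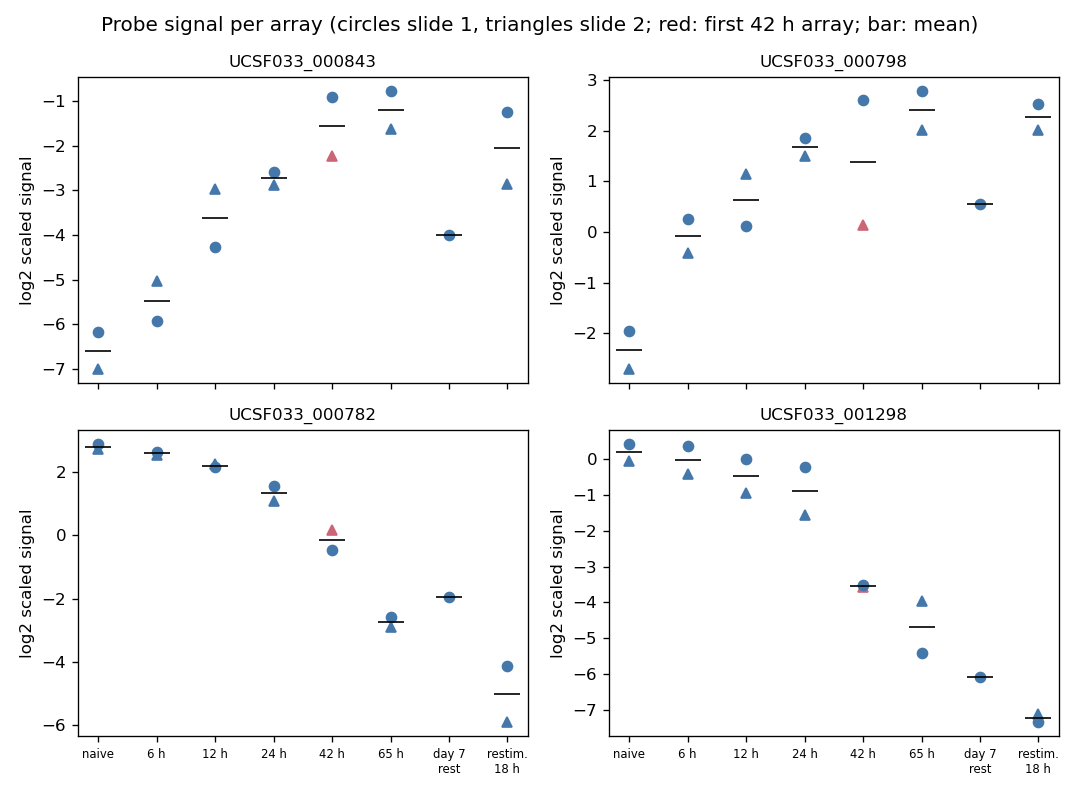
Scaled signal (log2, relative to the 75th percentile of each array) of probes UCSF033_000843, UCSF033_000798, UCSF033_000782 and UCSF033_001298 on each of the 15 arrays, by group. Circles are slide 1, triangles slide 2, the red point is the first 42 h array and the horizontal bar is the group mean; restim. stands for restimulated. UCSF033_000782 goes from 2.89 and 2.73 in naive cells to -2.57 and -2.90 at 65 h.

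The medians of the probes that rose or fell at 65 h lay on the same side of naive at each earlier time, weakly at 6 h and 12 h. Over the 188 probes that rose at 65 h without the first 42 h array, the median log2 difference from naive was 0.12 at 6 h, 0.48 at 12 h, 1.07 at 24 h, 1.87 at 42 h and 2.04 at 65 h. Over the 138 that fell it was -0.23, -0.56, -0.96, -1.70 and -1.72 at the same times. Of the 138, 59 were probes with 1 spot; the 79 in the value table had -0.25, -0.54, -0.95, -1.48 and -1.57. Of all these probes 65 also rose and 38 also fell at 24 h, against 13.9 and 6.10 for independent lists. None was called in the opposite direction at any time. The calls at both times share the naive arrays, which favours overlap in the same direction, so independent lists set too low a mark. These sets were chosen by their 65 h values, which favours a maximum at 65 h. The 100 probes highest at 65 h on slide 2 were therefore read on slide 1, with no array in both steps. There they lay above naive by a median of 0.14, 0.30, 1.49, 2.24 and 2.62 at 6, 12, 24, 42 and 65 h. The 100 lowest lay at -0.32, -0.68, -1.02, -1.91 and -2.19. All tested probes on those arrays had medians of 0, -0.003, 0, 0.28 and 0.62. Part of the rise of the highest after 24 h was therefore a shift of the median probe under the scaling. Chosen on slide 1 and read on slide 2, the highest lay at 0.16, 0.84, 1.41 and 2.60 at 6, 12, 24 and 65 h. The lowest lay at -0.14, -0.43, -1.15 and -2.06, and all tested probes had medians of -0.03, -0.06, 0 and 0.43. The lower quartile of the risen set was -0.04 at 6 h and 0 at 12 h, so not all of its probes were higher then. This reading across slides was added after the data were seen and carries no test between times. Both comparisons share the naive arrays. The fold changes at 24 h and 65 h correlated at r = 0.803 across probes, where unchanged groups simulated against the same naive arrays gave 0.492, and their covariance was 1.24 against 0.18. Taken from different slides, with no array in common, they correlated at r = 0.683 and 0.790, while 6 h and 65 h gave 0.337 and 0.325 and 12 h and 65 h gave 0.388 and 0.520.

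After rest in IL-2 to day 7 the cells differed from naive cells at 9 probes, 4 higher and 5 lower. UCSF033_000542 rose by 7.10 log2 (SE 1.11, limma adjusted p = 0.0182; 1 array against 2) and UCSF033_000543 by 6.97 log2 (SE 1.14, adjusted p = 0.0205). UCSF033_001298 fell by 6.28 log2 (SE 0.77, adjusted p = 0.0125) and UCSF033_001297 by 5.91 log2 (SE 0.92, adjusted p = 0.0182). The fit without the first 42 h array had 71 higher and 48 lower probes, including all 9 in the same direction. The slide as a block gave 9 higher and 15 lower, and without the first 42 h array 124 and 145. The single day 7 array was assumed to vary like the other groups. The split was 15 higher and 5 lower with the percentile over all probes, 12 and 14 after quantile normalization, 0 and 3 without scaling, and 58 and 71 in the value table. The count was 114 without the second 42 h array, 0 without either naive array (96 and 75 unadjusted), 5 without the second 6 h or the first 24 h array, and 14 without the second restimulated array.

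Against 65 h, limma called 0 probes at day 7 (41 at an unadjusted p under 0.05). The 100 probes highest at 65 h on slide 2 lay a median 1.82 log2 above naive at day 7 on slide 1. There the 65 h array had 2.62, and the 100 lowest lay at -1.75 at day 7 and -2.19 at 65 h. All tested probes had medians of 0.23 and 0.62, so part of the drop of the highest was a shift of the median probe. Each time is 1 array, with no test of the difference. When the first 42 h array was left out, 2 probes were higher and 4 lower at day 7 than at 65 h, and without the second 42 h array 4 passed. With the slide as a block as well as no first 42 h array 32 were higher and 17 lower. The value table gave 23 higher and 6 lower.

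Restimulated cells differed from naive cells at 138 probes, of which 88 rose and 50 fell. UCSF033_000906 rose by 6.16 log2 (SE 1.71, limma adjusted p = 0.0415, n = 2 each) and UCSF033_000905 by 6.12 log2 (SE 1.71, adjusted p = 0.0422), and both lost the call under 18 of the alternatives. UCSF033_000782 fell by 7.84 log2 (SE 0.55, adjusted p = 8.79e-05), with -7.04 on slide 1 and -8.65 on slide 2. UCSF033_001297 was lower (adjusted p = 0.000505), but was above background on 1 of the 2 restimulated arrays and at the floor on the other. Its size therefore depends on the floor: the log2 difference was -7.61 at the floor used, -8.08 at the lowered floor and -6.89 at the raised one.

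Of the 50 that fell, 23 were probes with 1 spot, against 3 of the 88 that rose. Without the first 42 h array these were 53 of the 134 that fell and 19 of the 228 that rose. All 138 probes went the same way on both slides, which their selection nearly fixes. Over all tested probes the fold changes of restimulated cells on the slides correlated at r = 0.865. In the fit without the first 42 h array 228 probes rose and 134 fell, including all 138, and the slide as a block gave 135 higher and 103 lower. Taken from different slides, the fold changes of restimulated and 65 h cells correlated at r = 0.854 and 0.841 across probes. The split was 29 higher and 42 lower with the percentile over all probes, 49 and 98 after quantile normalization, 0 and 5 without scaling, and 111 and 129 in the value table. The count was 358 without the second 42 h array, 24 and 18 without the first or second naive array, 71 and 70 without the 6 h arrays, 68 without either 24 h array, 80 without either 65 h array, and 79 and 62 without the restimulated arrays.

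Against the rested day 7 cells, limma called 0 probes after 18 h of restimulation, with 14 at an unadjusted p under 0.05. Without the first 42 h array the count was also 0, with 78 unadjusted. Leaving out the second restimulated array gave 1 lower probe. In the value table UCSF033_000772 was lower by 1.65 log2 (SE 0.24, adjusted p = 0.0362) and UCSF033_000782 by 2.54 log2 (SE 0.39, adjusted p = 0.0362). Both were named after their values were seen. The second response (restimulated minus rested) was set against the first (24 h minus naive), though the times of 18 h and 24 h differ. In limma 0 probes differed, with 15 at an unadjusted p under 0.05, and 0 with 74 unadjusted without the first 42 h array. The median SE of that difference was 1.11 log2 with all 15 arrays.

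The overall unscaled signal, which the scaling removes, was lower on most activated arrays. Over probes detected on all arrays the median log2 signal was 8.41 ± 0.46 in naive cells and 7.46 ± 0.66 at 65 h (SD, n = 2 each). The difference between the 10 arrays at 6 to 65 h and the 2 naive arrays was -0.53 log2 (two-sided exact permutation test, p = 0.470 over 66 splits), so it did not pass. Within slides and without the first 42 h array it was -0.74 (exact permutation p = 0.133 over 30 splits), and all 5 arrays at 24 h or later lay below the naive array of their slide. Leaving out the first or second naive array gave -0.86 and -0.20, and leaving out the first 42 h array -0.80. Without the first 42 h array and over value table probes alone, which hold none with 1 spot, it was -0.60.

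**Figure D3:**
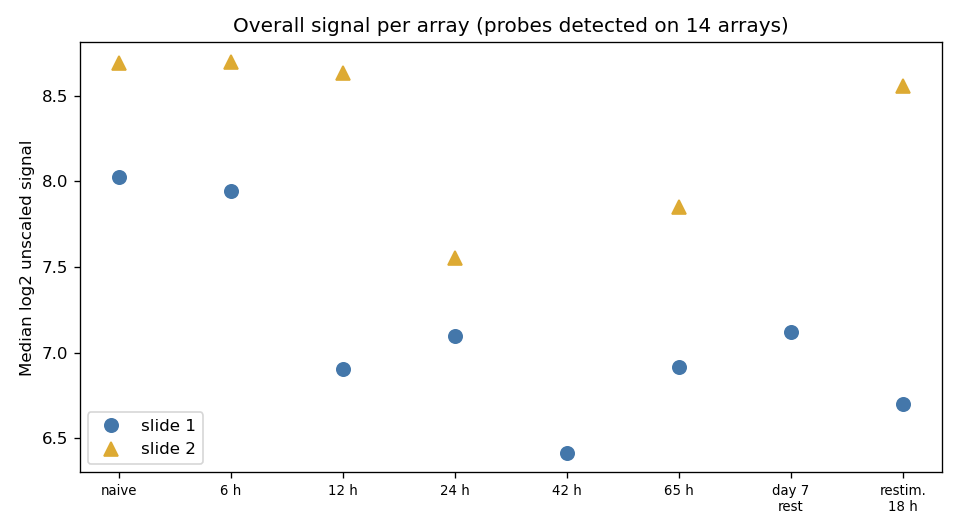
Median log2 unscaled signal per array over the probes detected on the 14 arrays left without the first 42 h array, by group, with circles for slide 1 and triangles for slide 2. Naive cells lie at 8.03 on slide 1 and 8.69 on slide 2, and 65 h cells at 6.92 and 7.85.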

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

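Normexp on median signal, the fit on value table probes alone, array weights, and the slide block without the first 42 h array were chosen after the data were seen; the other settings were planned. The 18 named probe results had 561 values under the alternatives: 457 kept direction and side of the threshold, 104 kept direction and lost the call, and 0 reversed. Where counts moved by over 1.5 times the cause was not tested, except that leaving out either 42 h array removed a discordant pair from the shared spread. With the percentile over all probes the counts were 0 at 24 h in limma (76 unadjusted), 87 at 65 h, 20 at day 7 against naive and 71 for restimulated against naive. Quantile normalization gave 6 at 24 h and 26 at day 7. Without scaling they were 0 at 24 h (34 unadjusted), 0 at 42 h (95 unadjusted), 14 at 65 h, 3 at day 7 and 5 restimulated. The value table gave 16 at 12 h, 101 at 24 h, 248 at 65 h, 29 for day 7 against 65 h, 129 for day 7 against naive, 2 for restimulated against day 7 and 240 for restimulated against naive. The total gene signal gave 17 at day 7, 50% of the floor 12 at 24 h, and a doubled floor 24 at day 7. With no filter on dim probes the counts were 2 at 6 h, 2 at 12 h, 109 at 42 h, 91 at 65 h, 70 restimulated and 2 for the second against the first response. Probes detected on all 15 arrays gave 13 at 24 h and 15 at day 7. The slide block gave 24 at day 7 and 238 restimulated, and the intensity trend 22 at day 7. Only the groups compared gave 81 at 24 h, 0 at 42 h (limma, 116 unadjusted) and 220 at 65 h.

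Of the settings chosen later, normexp gave 4 at 24 h and 452 at 42 h, and value table probes alone 112 at 42 h, 15 at day 7 and 86 restimulated. Array weights gave 9 at 6 h, 11 at 12 h, 223 at 24 h, 0 at 42 h (limma, 113 unadjusted), 323 at 65 h, 1 for day 7 against 65 h, 165 for day 7 against naive and 312 restimulated; both arrays of a pair get the same weight, 0.0723 at 42 h. Without the first 42 h array and with the slide block the counts were 11, 23, 248, 361 and 475 from 6 to 65 h, 49 for day 7 against 65 h, 269 for day 7 against naive and 493 restimulated. Leaving out each array in turn gave ranges of 0 to 6 at 6 h, 0 to 12 at 12 h, 0 to 104 at 24 h, 10 to 500 at 42 h, 33 to 326 at 65 h, 0 to 6 for day 7 against 65 h, 0 to 119 for day 7 against naive, 0 to 1 for restimulated against day 7, 18 to 362 for restimulated against naive and 0 for the second against the first response (limma, 15 unadjusted with all arrays). The overall signal ranged from -0.86 to -0.20. The replicate block gave 4 at day 7 against naive and moved no other count by over 1.5 times. By slide 13 of 15 pairs of groups correlated above 0.1, and in title order 7 of the 15 did. In these groups title order is slide order, except that it is swapped at 65 h and after restimulation. The lower number can follow from the slides, so it cannot show whether the numbers pair the samples.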

Other observations

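All tests in this part were chosen after the results were seen, and no biological explanation was tested for the patterns below, so activation itself stays open for the probes with 1 spot.

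On the first 42 h array many probes that are dim elsewhere were bright. Fluorescence raised over the whole surface is argued against, since the raw brightness around its spots was 14, against 13 to 15 on the other arrays. The raw brightness of its blank spots was 26, against 21.5 to 24. Its E1A and ETG control probes, read after background subtraction, had 267 against 3.74 to 5.84. The scanner file ranked probes unlike its own column of the value table (Spearman correlation 0.459, at least 0.999 on the other 14 arrays), which is consistent with a scan other than the one behind that table. A mislabelled sample stays open: over the 200 brightest probes it correlated with the second 42 h array at 0.849 and with the second restimulated array at 0.904. Its value table column correlated with that of the second 42 h array at 0.99, with 0.989 for the first 65 h and the second 24 h array and 0.938 at the lowest, but that column does not match the scanner file in question.

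Probes with 1 spot lay lower after activation: without the first 42 h array 59 of 152 fell and 1 rose at 65 h, where 79 of 693 value table probes fell and 183 rose. The split was less one-sided in restimulated cells, where 53 probes with 1 spot fell and 19 rose against naive. There 81 value table probes fell and 205 rose. All these counts are relative to the scaling. Unscaled, over probes detected on all 14 arrays, value table probes at 65 h had medians of -0.73 log2 (slide 1) and -0.52 (slide 2) against naive. Probes with 1 spot had -2.59 and -1.95. In restimulated cells the medians were -0.88 and 0.27 for value table probes, and -2.52 and -1.55 for probes with 1 spot. A level effect shared by all bright probes is argued against by a median 1.41 log2 below value table probes of matched naive level (difference -1.41). A difference between slides is argued against by 12 of 12 arrays that lay lower against the naive array of their own slide. All 8 arrays at 24 h or later had a gap to value table probes of -0.66 log2 or lower. The gaps at 6 h (-0.19 and -0.01) and at 12 h on slide 2 (-0.16) lay within the SD of a gap, 0.20. All 12 arrays share the 2 naive arrays. A steeper response of these probes to the brightness of an array is argued against as the whole cause: in 14 pairs of arrays of a slide the later array was brighter, and in 12 of them its 1-spot probes still lay further below value table probes, by a median difference of -0.67 log2 (SD of such a difference 0.29; the pairs share arrays). A part played by brightness stays open. Between the 2 arrays of a group, slide 2 minus slide 1, 1-spot probes differed more than value table probes in all 6 groups. The excess rose from 0.57 to 0.66, 0.82, 0.84 and 0.95 log2 as the brightness difference rose from 0.12 to 0.30, 0.40, 0.76 and 1.07. In restimulated cells it was 0.44 at 1.45. These 2 arrays always lie on different slides, so an offset between slides in the 1-spot probes cannot be told apart from brightness here. Against naive, brightness and activation were nearly confounded, since only 1 of the 12 arrays was brighter than the naive array of its slide. That array, restimulated on slide 2, had a gap of -1.82 log2. Other properties of the probes with 1 spot were not tested.

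Probes with consecutive numbers changed together. Over 387 such pairs of tested value table probes the median correlation across 14 arrays was 0.791, where 1000 draws of random pairs gave at most 0.241. In the fit without the first 42 h array both probes were called at 65 h in 116 pairs, in the same direction in 108. In 99 pairs only 1 probe was called. A candidate explanation is that consecutive numbers belong to the same target, in which case the counts of probes overstate the counts of miRNAs. Named probes with consecutive numbers, such as the 2 called at 24 h with all 15 arrays, would then not be separate results.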
